A study of Arabidopsis thaliana with 4 samples.

How the data were processed

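RNA bound in anti-Myc immunoprecipitates of crosslinked Arabidopsis plants was sequenced in 4 libraries, 2 labelled control RIP and 2 labelled CLF RIP. The deposited tables give 1 FPKM value per locus. Per the submitters' processing notes, Trimmomatic and TopHat2 2.0.10 were used with the TAIR10 genome, and the program that made the FPKM is not given in the sources used here. Loci carry either a TAIR10 gene identifier or a serial number of their own library. The tables' names give the opposite groups from the labels, and the labels were used.

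Coordinates are those of the tables. Gene names and RNA classes came from a RefSeq table of TAIR10.1, which held 21363 of the nuclear identifiers and lacked 414, and which names no transposable element class. Genes under their own identifier in all 4 libraries (14960, of which 7999 were listed at 0 throughout) gave the counts of genes, the named genes and the correlations. For CLF, gene lists and RNA classes, loci with serial numbers were also matched to genes by a reciprocal overlap of at least 0.8 in all 4 libraries, with a span of at least 300 bp and 1 gene per locus. This gave 27069 genes after 199 were left out because a locus with a serial number had a value at or above that of 1 read on a 75 bp locus. Loci under their own identifier were not left out for this, and AT2G16586 was kept with such values. Both joining rules were chosen after the tables were seen, on how well libraries of 1 group resembled each other. The tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

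The value of 1 read on a 75 bp locus was 10940 and 11294 FPKM in the control RIP libraries and 25693 and 25765 FPKM in the CLF RIP libraries. From unspliced loci with few reads, the scaling depth was fitted so that values became whole reads, and 90.0% to 92.8% were whole within 0.1. For genes of up to 180 bp, the lowest value above 0 among loci of the same span, taken relative to the value of 1 read on a 75 bp locus, was read as 1 read, at 94 of 105 spans where at least 90% of low values were whole multiples of it within 0.03. For the comparison of libraries within a group, genes of at least 350 bp under their own identifier were used if their values were whole reads within 0.08 in all libraries, with at least 0.5 and at most 150 reads in each and at least 12 over all. A count test over all genes was not run, since transcript lengths of spliced genes were not used here. Values of short loci are large for few reads, and an exact 0 can be a failed estimate, so such genes are said to be listed at 0.

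Genes with at least 1 FPKM in at least 2 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust prior), with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds on this scale understate the change of low genes. Lists were tested with camera at a correlation of 0.01 and with an estimated correlation, and set against 10000 random lists matched on mean level. RNA classes needed at least 5 detected members. Genes named by rule were CLF and UNE15, the 3 members of each list or class with the smallest p, and the most abundant genes. The rule also named the 10 largest folds per direction among genes past the threshold. For these, the groups did not overlap and the higher group mean reached 5 FPKM. Genes outside the rule are named too, such as RING1B, RD22, P5CS1, examples of at least 300 bp and some evening and morning genes.

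The fit was tested on simulated data with a seeded set of changed genes. Values were drawn from normal distributions on the log2 scale with the fit's own variances, without exact zeros, filter or counting of reads. The false calls below therefore do not carry over to the deposited values. In the simulated comparison over 2462 genes it recovered 36 of 78 genes changed 2-fold, 58 of 62 changed 4-fold and 58 of 60 changed 16-fold, with 4 false calls. Over 14668 genes it recovered 0 of 68, 7 of 59 and 54 of 73, with 3 false calls. The slope of estimated on true changes was 1.01 in both. Alternatives changed the filter, pseudocount, scaling, prior, threshold, pairing, joining rule and libraries used, each apart from the others. The prior's trend and robust setting were switched off together, and leaving out structural RNA genes came with rescaling. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.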

Results

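RNA immunoprecipitation with sequencing was used to collect RNA bound to CURLY LEAF (CLF), a histone methyltransferase of Polycomb repressive complex 2, from Arabidopsis plants aged 3 weeks. There were 2 control RIP libraries from wild-type Col-0 plants and 2 CLF RIP libraries from clf-28 plants that carried Myc-tagged CLF, all taken with an anti-Myc antibody. The comparison asks which RNAs differ in level between the CLF RIP and the control RIP. The groups follow the sample labels. The names of the deposited tables give the opposite groups, so every direction below turns if the labels are wrong.

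The deposited values were FPKM per locus. The control RIP libraries listed 67292 and 67135 loci and the CLF RIP libraries 67357 and 67210. From the value of 1 read, the FPKM were estimated to be scaled to 10.0 and 9.70 M fragments in the control RIP libraries and to 4.26 and 4.25 M in the CLF RIP libraries. The value of 1 read was thus 2.31 times as large in the CLF RIP.

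Over 1282 unspliced genes selected for whole reads (within 0.08) and at most 150 reads in each library, the libraries of a group differed by no more than the sampling noise. Chi-square over degrees of freedom was 1.04 for the control RIP pair and 0.925 for the CLF RIP pair, and 2.92 to 3.03 between groups. The upper 95% bound on any further spread of these genes within a pair was a coefficient of variation of 6.98% in the control RIP and 0.821% in the CLF RIP. The selection also required at least 0.5 reads in each library, so genes with 0 reads in any library were dropped. That can lower chi-square and the bounds of both pairs. Chi-square of the CLF RIP pair lay below its degrees of freedom, which by itself makes the bound small. The bounds therefore do not show that the CLF RIP pair was the tighter one. Genes outside this selection were not covered by that test and lay far apart within a pair in some cases. RING1B (AT1G03770), chosen after its values were seen, was listed at 1.75 and 155 FPKM in the CLF RIP libraries. Nothing in the labels says that the libraries of a group came from separate plants, so the limma p-values below measure only the spread between these libraries, which can be technical. Across 2462 genes the Pearson correlation was 0.926 within the control RIP pair and 0.828 within the CLF RIP pair, and 0.723 to 0.765 between groups. Genes are not independent replicates, and this gene set came from a joining rule chosen on the likeness of libraries within groups, so the order of these correlations was partly selected for.

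CLF itself (AT2G23380, on chromosome 2 from 9955553 to 9960359 in TAIR10, and to 9960381 in control RIP replicate 1) was listed at 25.9 and 27.1 FPKM in the control RIP libraries and at 4.24 and 25.7 FPKM in the CLF RIP libraries. The CLF log2 fold change was -1.22 and missed the threshold, with a limma Benjamini-Hochberg adjusted p of 0.451. Its direction was lower under every scaling tried, but it was -0.04 without CLF RIP replicate 1 and -2.39 without CLF RIP replicate 2, so 1 library set its size. Its spread between the CLF RIP libraries left open which groups the tables hold.

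UNE15 (AT4G13560), the gene named in the series title, had no locus that matched in all 4 libraries and was not tested. Its region on chromosome 4 held 5 loci of at least 200 bp in each control RIP library and 5 and 6 in the CLF RIP libraries, all between 7879517 and 7883781. They were listed at 3.69 to 16.6 FPKM and 3.79 to 35.9 FPKM in the control RIP libraries and at 9.16 to 20.6 FPKM and 7.69 to 46.5 FPKM in the CLF RIP libraries. Their spans differed between libraries and none was identified as the UNE15 transcript, so no fold is given. The overlapping noncoding RNA OLE was not analysed here.

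Among 2462 genes listed under their own identifier in all libraries, 284 genes were higher and 204 were lower in the CLF RIP by limma at a Benjamini-Hochberg adjusted p under 0.05, and 971 had an unadjusted p under 0.05. Among the genes past the adjusted threshold, 20 of the higher ones were listed at 0 in the control RIP and 39 of the lower ones at 0 in the CLF RIP. At least 2-fold apart with no overlap between groups were 182 higher and 166 lower genes. Irrespective of fold, 39.7% of genes lay above and 25.5% below without overlap, where chance gives 16.7% each. The joining rule was chosen on the likeness of libraries within groups, so these shares and the counts of calls may be raised by that choice. The share of higher genes among the calls was 58.2% as deposited, 48.4% after quantile normalization, 40.3% after median-of-ratios scaling and 88.6% with structural RNA genes left out and the rest rescaled. The median log2 fold change of all these genes was 0.11, 0.02, -0.03 and 0.51 in turn. The last setting rescaled by summed FPKM, which included AT2G16586 at 14528 and 14639 FPKM in the control RIP against 3588 and 3651 FPKM in the CLF RIP. How far this gene moved the balance was not tested. Limma called 0 genes without control RIP replicate 1, where 468 had an unadjusted p under 0.05, and 0 without control RIP replicate 2, where 448 did. It called 182 higher and 240 lower genes without CLF RIP replicate 1, and 167 higher and 253 lower genes without CLF RIP replicate 2. The share of higher genes among the calls was then 43.1% and 39.8%, so the balance between directions turned.

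The genes with the largest folds among those past the threshold were mostly very short. Most of them rested on very few reads, and limma's spread does not carry the counting error of such values. Of 10 higher genes, 8 were listed at 0 in the control RIP and 7 spanned under 300 bp. They included the small nucleolar RNA genes AT1G19376 at 2374 and 3571 FPKM and SNOR77 at 623 and 398 FPKM, and the microRNA genes MIR779 at 393 and 350.02 FPKM and MIR861 at 58.9 and 118 FPKM in the CLF RIP libraries. These values were 2 and 3 reads for AT1G19376, 11 and 7 for SNOR77, 18 and 16 for MIR779 and 1 and 2 for MIR861. AT5G17847 was listed at 66.3 and 133 FPKM (1 and 2 reads), AT4G31355 at 75.1 and 75.4 FPKM (1 read each), AT4G08876 at 11.1 and 11.1 FPKM and the noncoding RNA AT1G36992 at 12.9 and 8.36 FPKM. MIR847 was listed at 0 and 2.48 FPKM in the control RIP and at 45.2 and 22.7 FPKM in the CLF RIP. Of 10 lower genes, 9 were listed at 0 in the CLF RIP. The microRNA gene MIR160b, on chromosome 4 from 9888986 to 9889066, was listed at 1402 and 1447 FPKM in the control RIP, which was 1 read in each library. AT1G35143, AT3G61117, AT3G30769, AT5G49334, AT3G50682, AT3G06142, AT4G05071 and AT4G25386 lay between 13.9 and 64.0 FPKM there, or 1 to 4 reads per library. Zeros against so few reads, in CLF RIP libraries of lower depth, do not show that these genes differed. The pseudogene AT4G06477 was at 34.4 and 32.9 FPKM in the control RIP and at 1.88 and 2.74 FPKM in the CLF RIP, a log2 fold change of -3.40 (SE 0.17).

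The same rule over genes with spans of at least 300 bp and values above 0 in both groups was chosen after their values were seen. It gave 10 genes per direction, of which examples picked by hand follow. AT5G23240 was listed at 4.04 and 4.14 FPKM in the control RIP and at 51.7 and 50.7 FPKM in the CLF RIP (log2 fold change 3.36, SE 0.09). The sulfotransferase gene ST2A rose from 2.70 and 3.63 FPKM to 38.95 and 39.1 FPKM. CYP94B3, which oxidises a jasmonate conjugate, rose from 1.007 and 0.970 FPKM to 13.4 and 13.8 FPKM, and the transcription factor gene ERF53 from 0.645 and 0.951 FPKM to 9.74 and 8.68 FPKM. The spliceosomal RNA gene U2.6 rose from 113 and 90.4 FPKM to 561 and 593 FPKM. In the other direction, PAP1 (AT2G01180) fell from 135 and 143 FPKM to 20.6 and 23.1 FPKM. The noncoding RNA gene AT1G15002 fell from 372 and 365 FPKM to 63.5 and 72.6 FPKM. AT2G16586 was listed at 14528 and 14639 FPKM against 3588 and 3651 FPKM and is counted among the lower genes. Both control RIP values lay above that of 1 read on a 75 bp locus, and less that value they were 3588 and 3345 FPKM, so the difference was no larger than 1 such read per library.

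Few members of the fixed gene lists carried their own identifier in all libraries, so lists and RNA classes were compared over 14668 genes matched by locus. In this set 101 genes were higher and 81 lower by limma, and 3626 had an unadjusted p under 0.05. Its joining rule was also chosen on the likeness of libraries within groups, which may raise these counts. The counts were 76 and 94 after quantile normalization, 84 and 115 after median-of-ratios scaling and 48 and 73 with structural RNA genes left out. Limma called 0 genes without control RIP replicate 1 or 2, where 1672 and 1632 had an unadjusted p under 0.05. It called 0 higher and 1 lower without CLF RIP replicate 1 or 2, where 3534 and 3477 did, and 0 of both without the trend and robust prior, where 3718 did. Without a filter it called 0 and 1, and at a pseudocount of 5 it called 0 and 2. Counts of list members past the threshold over all genes rest on this fit. The median log2 fold change of all genes was 0.25. It was 0.02 after quantile normalization, 0.01 after median-of-ratios scaling and -0.13 with structural RNA genes left out. In simulated data this fit recovered 0 of 68 genes changed 2-fold, 7 of 59 changed 4-fold and 54 of 73 changed 16-fold, so missing the threshold does not show that a gene was level. All 12 lists are described as deposited, with 2 libraries per group.

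Nuclear-encoded photosynthesis genes were lower in the CLF RIP. All 16 detected members lay below 0, 8 of them fell over all genes tested and 15 when adjusted over the list alone, and 8 did not pass. RBCS1A, a Rubisco small subunit gene, fell from 1308 and 1290 FPKM to 406 and 396 FPKM (log2 fold change -1.69, SE 0.04). The light-harvesting genes LHCB1.3, from 953 and 958 FPKM to 422 and 427 FPKM, and LHCB1.1, from 468 and 441 FPKM to 120 and 120 FPKM, fell too. Near-identical copies such as LHCB1.1 and LHCB1.3 can share reads, so their single values are uncertain. The list's median was -1.24, below all of 10000 random lists matched on mean level. The camera adjusted p over lists was 9.07e-20, and 0.117 with an estimated correlation.

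Genes of osmotic, cold and ABA response were higher in the CLF RIP. Of 18 detected members, 16 lay above 0, 3 rose, 0 fell and 15 did not pass, and 12 were higher when adjusted over the list alone. The 2 below 0 were RD22, at 125 and 195 FPKM against 88.9 and 85.6 FPKM, and P5CS1, at 38.2 and 30.2 FPKM against 7.66 and 39.4 FPKM. RD29A, a dehydration-responsive gene, rose from 5.05 and 6.38 FPKM to 115 and 116 FPKM (log2 fold change 4.12, SE 0.21). The dehydrin genes COR47, from 91.7 and 88.0 FPKM to 289 and 310.5 FPKM, and ERD10, from 76.2 and 75.3 FPKM to 216 and 209 FPKM, rose too. The list's median was 1.22, with a camera adjusted p of 0.000142, and of 0.186 with an estimated correlation.

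**Figure D1:**
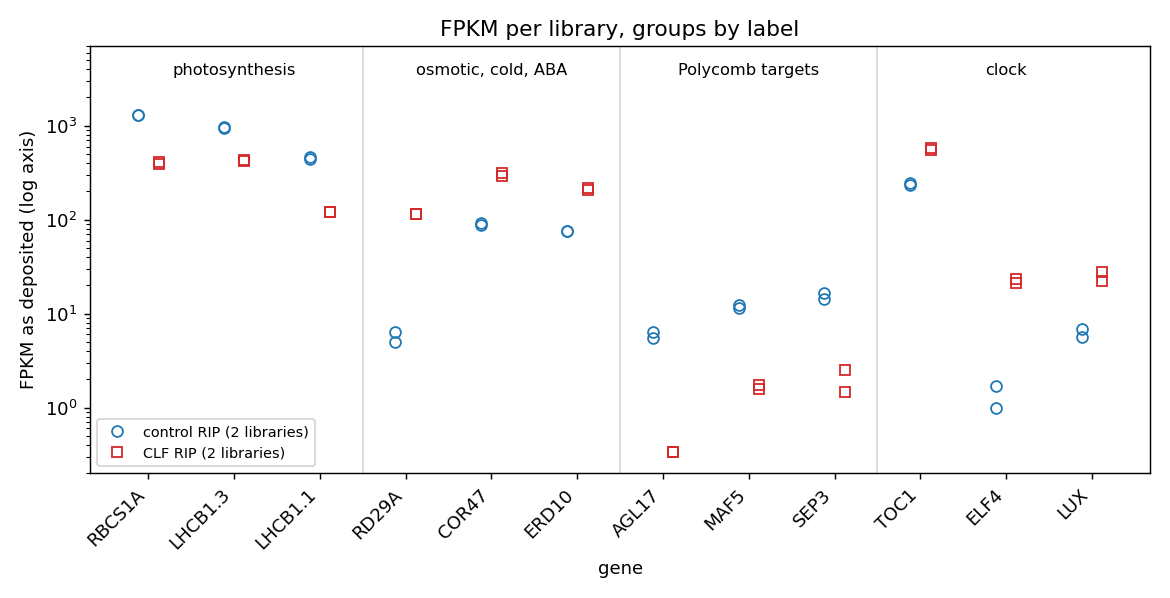
FPKM as deposited (log axis) of the 3 members with the smallest p in each of 4 gene lists, with 1 point per library, circles for control RIP and squares for CLF RIP by label. RBCS1A lies at 1308 and 1290 FPKM in the control RIP and at 406 and 396 FPKM in the CLF RIP, and RD29A at 5.05 and 6.38 FPKM against 115 and 116 FPKM.

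Developmental genes known as Polycomb targets were lower in the CLF RIP. Of 18 detected members, 17 lay below 0, 2 fell and 16 did not pass, and 8 were lower when adjusted over the list alone. The MADS-box genes AGL17, from 6.35 and 5.46 FPKM to 0.338 and 0.339 FPKM, and MAF5, from 12.3 and 11.6 FPKM to 1.73 and 1.60 FPKM, fell. The CLF RIP values of AGL17 lay below 1 FPKM in libraries of lower depth, and its reads were not counted here. They can rest on few reads, and their small spread (SD 0.00067) can come from equal low counts, an error limma's spread does not carry. The floral gene SEP3 was at 16.7 and 14.3 FPKM against 2.52 and 1.47 FPKM and missed the threshold. The list's median was -1.26, with a camera adjusted p of 6.26e-10, and of 0.119 with an estimated correlation.

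Of 13 detected PRC2 and PRC1 components, 0 passed in limma over all genes tested or adjusted over the list alone, 1 had an unadjusted p under 0.05, and the list's median of 0.48 lay at percentile 74.7 of matched random lists (camera adjusted p 0.734). The list's shift from the median of all genes was 0.24, and was 0.029 without CLF RIP replicate 1 and 0.086 without CLF RIP replicate 2 or control RIP replicate 1. VEL1 was at 22.0 and 26.9 FPKM against 12.9 and 8.59 FPKM, MSI1 at 4.46 and 5.01 FPKM against 8.71 and 6.30 FPKM, and RING1A at 4.19 and 8.12 FPKM against 8.46 and 13.2 FPKM. Of 14 detected histone genes 0 passed in limma, 5 had an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 1 lower. Of the 14 genes, 2 lay above and 12 below 0. The median was -0.52, with a camera adjusted p of 0.00185, and of 0.296 with an estimated correlation. By fry, which compares no other genes, the histone adjusted p was 0.0767. HTB2 was at 92.4 and 97.2 FPKM against 57.3 and 52.3 FPKM, HTA1 at 22.8 and 24.0 FPKM against 48.1 and 46.7 FPKM, and the H4 gene AT3G46320 at 13.8 and 15.6 FPKM against 6.80 and 8.34 FPKM.

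Of 8 detected circadian clock genes, 2 rose and 6 did not pass, and adjusted over the list alone 3 were higher and 2 lower. TOC1, an evening clock component, rose from 236 and 245 FPKM to 575 and 554 FPKM, and ELF4 rose from 1.70 and 1.00 FPKM to 23.4 and 21.2 FPKM. LUX was at 5.71 and 6.94 FPKM against 27.8 and 22.3 FPKM and missed the threshold. The median of the list was -0.03, its mean 0.31, and camera gave the upward direction with an adjusted p of 0.893, so the signs differ.

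Of 9 detected genes of the rapid stress and wounding response, 1 rose and 8 did not pass, with 3 above and 6 below 0. Adjusted over the list alone, 2 were higher and 5 lower. JAZ10, a repressor of jasmonate signalling, rose from 51.8 and 47.8 FPKM to 159 and 159 FPKM. WRKY40 was at 372 and 338 FPKM against 195 and 213 FPKM, and JAZ1 at 81.1 and 76.8 FPKM against 138 and 148 FPKM. The median was -0.86, with a camera adjusted p of 0.0263, and of 0.296 with an estimated correlation. The call also ended under each other scaling, with adjusted p of 0.0757 (quantile), 0.0739 (median-of-ratios) and 0.0827 (structural RNA genes left out), on ranks (0.135) and at the longer span minimum (0.0501).

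Of 7 detected heat shock genes 0 passed in limma, 3 had an unadjusted p under 0.05 and 1 was higher when adjusted over the list alone. All 7 lay above 0, with a median of 0.92 at percentile 99.0 of matched random lists and a camera adjusted p of 0.0901. Their shift from the median of all genes was 0.67, but 0.046 without CLF RIP replicate 1, 0.26 without control RIP replicate 1 and -0.024 with a stricter filter on low values. The heat stress factor gene HSFA2 was at 0.0843 and 0 FPKM against 2.51 and 5.73 FPKM, HSP101 at 1.39 and 1.51 FPKM against 4.33 and 3.04 FPKM, and HSP70 at 0.481 and 0.248 FPKM against 2.37 and 1.25 FPKM. Of 11 detected genes of pathogen and jasmonate defence 0 passed, also when adjusted over the list alone, and 4 had an unadjusted p under 0.05. Their median was -0.01, with a camera adjusted p of 0.305, and their shift of -0.25 from the median of all genes was -0.060 without control RIP replicate 1. LOX2 was at 208 and 227 FPKM against 285 and 286 FPKM, PR1 at 1.45 and 1.68 FPKM against 0 and 0.426 FPKM, and VSP1 at 11.1 and 8.59 FPKM against 5.68 and 4.88 FPKM. LOX2 lay lower in the CLF RIP with structural RNA genes left out.

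Of 13 detected reference mRNAs 2 lay above and 11 below 0. Of the 13, 0 passed, also when adjusted over the list alone, and 4 had an unadjusted p under 0.05. Their median of -0.19 lay at percentile 8.89 of matched random lists, with a camera adjusted p of 0.0166, of 0.299 with an estimated correlation, of 0.105 without control RIP replicate 1 and of 0.0963 at a reciprocal overlap of 0.95. By fry it was 0.114. GAPC2 was at 125 and 127 FPKM against 82.2 and 77.1 FPKM, UBQ5 at 82.3 and 88.5 FPKM against 56.7 and 54.96 FPKM, and SAND at 10.2 and 11.96 FPKM against 41.2 and 24.7 FPKM. Of 4 detected root markers 0 passed, 1 had an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone. The median was -0.06, with a camera adjusted p of 0.205. PHO1 was at 14.2 and 18.0 FPKM against 3.46 and 3.47 FPKM, SHR at 1.98 and 2.74 FPKM against 1.99 and 1.73 FPKM, and SCR at 3.34 and 2.95 FPKM against 3.67 and 3.68 FPKM, where SCR turned lower under each other scaling. Of 4 detected loci of rRNA and spliceosomal RNA 0 passed, 3 had an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 2 lower. Their median was -0.29, with a camera adjusted p of 0.311. The U6 gene AT5G46315 was at 6.38 and 5.41 FPKM against 0.333 and 0 FPKM and missed the threshold in this set. Among the 2462 genes under their own identifier it passed in limma (log2 fold change -2.57, adjusted p 0.0115). The U6 gene AT3G14735 was at 1.03 and 1.23 FPKM and listed at 0 in the CLF RIP. The U2 gene AT3G57645 was at 8.53 and 7.55 FPKM against 18.96 and 17.2 FPKM.

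**Figure D2:**
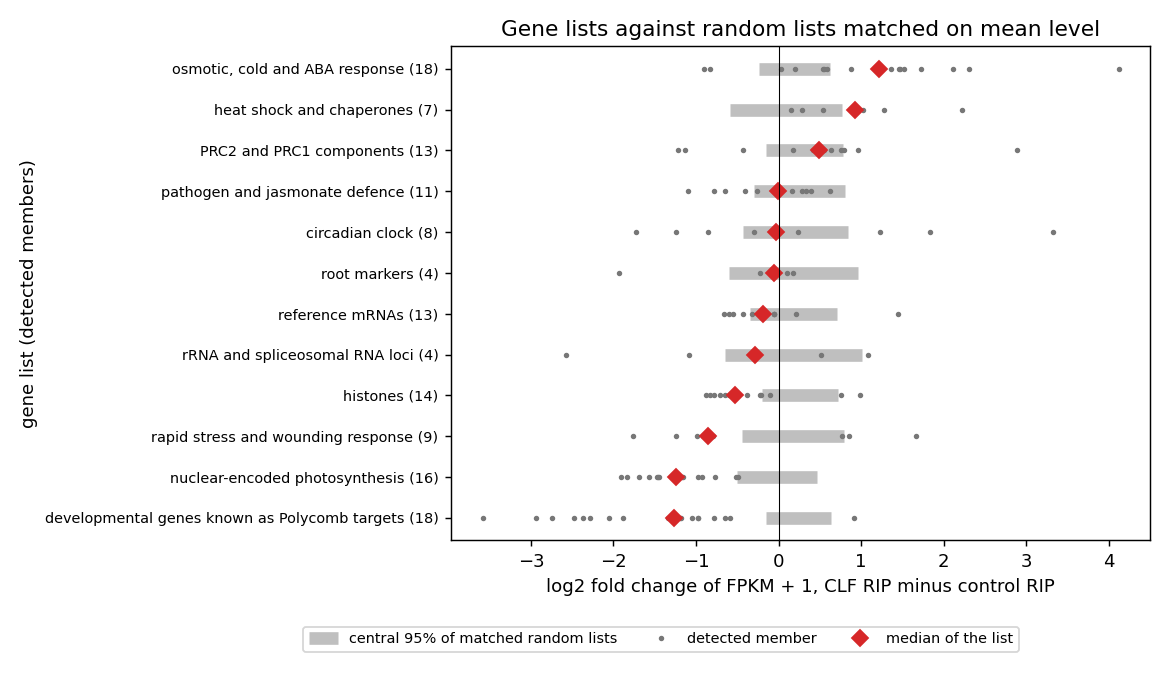
Log2 fold change of FPKM + 1, CLF RIP minus control RIP (x axis), for the 12 gene lists (y axis), with dots for detected members, diamonds for list medians and grey bars for the central 95% of random lists matched on mean level. The medians run from -1.26 for Polycomb targets to 1.22 for osmotic, cold and ABA response.

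Loci without a gene identifier that spanned up to 100 bp held 97.7% of the summed FPKM in both control RIP libraries and 98.7% and 98.6% in the CLF RIP libraries. The difference between groups of 0.967 points was 0.0784 points without the 10 most abundant loci. Protein-coding genes under their own identifier held 0.0249% and 0.0227% in the control RIP and 0.00993% and 0.00982% in the CLF RIP. Their summed values were 58927 and 54734 FPKM against 52318 and 51069 FPKM. The short loci without a gene identifier summed to 231499715 and 235380344 FPKM against 520404069 and 512816878 FPKM. The lower share thus came mostly from the larger sum of short loci in the CLF RIP, where the value of 1 read was 2.31 times as large. All 271 organelle loci were listed at 0 in each library. The most abundant locus in each library overlapped the spliceosomal RNA gene U1.5 (AT1G08115, chromosome 1 from 2538076 to 2538237), at 1679390 and 1615290 FPKM in the control RIP and 775766 and 759568 FPKM in the CLF RIP. The noncoding RNA gene AT1G07017 was overlapped by the next locus in each library, at 594381 and 546513 FPKM against 382763 and 614260 FPKM, and AT5G07745 stood at 218298 and 231205 FPKM against 180011 and 217341 FPKM. Such sums weigh short loci heavily and are not shares of molecules.

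Ribosomal protein genes were taken as the 67 nuclear protein-coding genes with that term in their symbol or synonyms, so those named otherwise were not included. The term does not tell genes of cytosolic ribosomes from those of plastid or mitochondrial ones, and these were not separated. The set was lower, with a median of -0.29 over 48 detected members, of which 34 lay below 0. Of the 48, 0 passed in limma or when adjusted over the list alone, and 13 had an unadjusted p under 0.05. PSRP6 was at 48.1 and 41.4 FPKM against 9.96 and 11.3 FPKM, RPL27AB at 94.99 and 98.1 FPKM against 40.8 and 47.5 FPKM, and SSR16 at 107 and 113 FPKM against 51.4 and 59.5 FPKM. Their camera adjusted p over classes was 5.29e-05, and 0.167 with an estimated correlation. Over 202 noncoding RNA genes 4 rose, 2 fell and 196 did not pass, and adjusted over the list alone 12 were higher and 6 lower. AT3G07215 rose from 64.7 and 61.4 FPKM to 187 and 205 FPKM. Over 259 pseudogenes 2 rose, 2 fell and 255 did not pass, and adjusted over the list alone 10 were higher and 8 lower. AT3G43828 rose from 4.76 and 4.67 FPKM to 46.4 and 45.99 FPKM. AT1G73445 was listed at 0 in the control RIP and at 4.89 and 7.13 FPKM in the CLF RIP. Of 6 snRNA genes 2 rose and 1 fell, and adjusted over the list alone 3 were higher and 3 lower. The span minimum of 300 bp leaves out shorter loci. Detected were 202 of 4288 noncoding RNA genes, 259 of 4843 pseudogenes and 6 of 82 snRNA genes, so these results do not stand for whole classes. U4.2 fell from 1152 and 1125 FPKM to 742 and 753 FPKM, and U2.3 rose from 153 and 157 FPKM to 363 and 349.8 FPKM. Over 14185 protein-coding genes 92 rose and 76 fell, and 92 and 75 did when adjusted over the list alone. Among those with the smallest p, PIT1 (AT4G02075) was listed at 0 in the control RIP and at 96.5 and 104 FPKM in the CLF RIP. The camera adjusted p was 0.866 for each of these 4 classes. Its direction, taken against all other genes, was down for noncoding, snRNA and protein-coding genes although their medians of 0.23, 0.24 and 0.25 were above 0.

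Only 4 of 326 microRNA primary transcripts were detected with the span minimum of 300 bp, too few for a class test. Of these 4, 1 rose and 2 were higher when adjusted over the list alone. MIR824 rose from 35.8 and 36.4 FPKM to 107 and 102 FPKM, while MIR402 was at 2.88 and 4.95 FPKM against 20.3 and 42.9 FPKM and MIR414 at 6.94 and 8.50 FPKM against 28.8 and 9.08 FPKM. In the same set 2 of 287 small nucleolar RNA genes and 0 of 625 tRNA genes were detected. The small nucleolar RNA genes U3B, at 22.6 and 23.4 FPKM against 33.2 and 33.3 FPKM, and U3D, at 73.5 and 47.7 FPKM against 115 and 90.4 FPKM, did not pass.

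Under their own identifiers, the most abundant gene of small nucleolar RNA by FPKM was AT2G35744. It fell from 43378 and 44782 FPKM to 10724 and 16130.5 FPKM. AT2G35744 spanned 79 bp and its reads were not counted here. Its CLF RIP values lay below that of 1 read on a 75 bp locus, so they can rest on few reads. The most abundant gene of snRNA was U12, which fell from 3472 and 3230.5 FPKM to 1354 and 1067 FPKM. The noncoding RNA gene AT1G15405 fell from 552 and 519 FPKM to 327 and 275 FPKM. The pseudogene SADHU1-1 rose from 25.6 and 27.4 FPKM to 37.8 and 38.5 FPKM. The pseudogene AT4G04692, at 67.95 and 64.4 FPKM against 67.6 and 82.6 FPKM, did not pass. The tRNA gene AT4G11213, at 793 and 819 FPKM against 3725 and 0 FPKM, overlapped between groups. It spanned 84 bp, and its value in each library lay below that of 1 read on a 75 bp locus.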

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

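The search for signal away from genes was chosen after the tables were seen. A locus on chromosome 1 from 4088892 to 4089296, at least 300 bp from any gene of the RefSeq table, was listed at 8.92 FPKM in CLF RIP replicate 1. CLF RIP replicate 2 had an overlapping locus from 4088769 to 4089008 at 19.6 FPKM, and neither control RIP library had a locus above 0 there. It lay outside the genes compared and above the control RIP. Of 103 loci of at least 350 bp away from genes in CLF RIP replicate 1, 83 overlapped a locus of at least 200 bp in CLF RIP replicate 2 and 1 of these overlapped none in the control RIP. The value in replicate 1 corresponds to about 7.51 reads if unspliced, which is not whole, so that count is uncertain. Reads in replicate 2 were not counted. So few reads at 1 locus picked from 103 do not show a difference between groups.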

How the results depend on the processing

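The alternatives on the joining of loci, the spans, values on the read-length step, genes above 0 in all libraries and camera on ranks were chosen after seeing the data. The lower photosynthesis genes and Polycomb targets and the higher osmotic, cold and ABA genes kept their direction and their side of the threshold under every alternative run except the estimated correlation. The replicate numbers share only a number: deviations of same-numbered libraries correlated at 0.006 over 2462 genes, and with the replicate number as a block 44 genes were higher and 41 lower, of which 84 were among the 488; matched by locus it called 0 higher and 1 lower. Without a filter 27 were higher and 23 lower. Median-of-ratios scaling gave 171 higher genes, and structural RNA genes left out gave 868 higher and 112 lower. A 2-fold minimum gave 140 and 122, an adjusted p under 0.1 gave 507 and 335, and matching by locus 101 and 81. Leaving out 1 library gave 0 to 182 higher and 0 to 253 lower genes, where the lone library was taken to vary like the other group. Counts of genes apart without overlap were 524 and 367 at 1.5-fold, 32 and 26 at 4-fold, 358 and 261 at a pseudocount of 0.1, 37 and 47 at a pseudocount of 5, 91 and 95 under the stricter filter, and 1982 and 848 matched by locus. The mean correlation within groups was 0.775 at a pseudocount of 0.1.

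Shifts of list medians from the median of all genes are given where the test's direction turned or its call changed, and the cause was not tested. With an estimated correlation the calls ended for Polycomb targets (-1.51), histones (-0.77), photosynthesis (-1.49), osmotic, cold and ABA response (0.97), stress and wounding (-1.11), reference mRNAs (-0.44) and ribosomal proteins (-0.54). The stress list's call also ended under quantile (-1.20) and median-of-ratios (-1.15) scaling, with structural RNA left out (-1.18), at the longer span minimum (-1.10) and on ranks, and that of reference mRNAs at a reciprocal overlap of 0.95 (-0.45). By fry, which compares no other genes, the calls of histones and reference mRNAs ended, and those of the clock (-0.28), heat shock (0.67), root (-0.31), rRNA and spliceosomal (-0.54), pseudogene (-0.0086), protein-coding and noncoding sets appeared, the last 2 in the turned direction. The heat shock list also passed with the replicate block. The clock's direction turned with the block, without the trend and robust prior, on ranks, at an overlap of 0.95 (-0.53) and at the longer span minimum (-0.58). Protein-coding genes turned with the block and by fry (-3.2e-05), without a filter (0.026) and under own identifiers (0.0028). Noncoding genes turned without a filter (0.065), by fry and on ranks (-0.022) and under own identifiers (0.10). Pseudogenes turned without a filter (-0.12) and under own identifiers (-0.021), and snRNA under the stricter filter (0.78) and by fry (-0.012). Leaving out 1 library gave -0.33 to -0.17 for the clock, 0.029 to 0.35 for PRC components, -0.56 to -0.40 for reference mRNAs, -0.0015 to 0.00013 for protein-coding, -0.067 to 0.033 for noncoding and -0.0017 to 0.047 for pseudogenes. LOX2 turned to -0.055 with structural RNA left out. SCR turned to -0.0020, -0.049 and -0.18 under quantile and median-of-ratios scaling and with structural RNA left out. Without the 10 most abundant loci the CLF RIP minus control RIP difference in the share of summed FPKM was -0.0398 in place of -0.904 points for loci with serial numbers over 100 bp, and 0.0784 in place of 0.967 for those up to 100 bp. UNE15 gave no value under any alternative, and a count test was not run. The CLF RIP libraries had the lower depth, which limits the detection of low genes there.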

Other observations

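The tests on photosynthesis genes and on long loci were chosen after the results were seen, and so was the one on clock genes outside the fixed lists. The test on all evening and morning genes was written before their single values were looked at.

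Among genes known to peak towards evening, FKF1 was at 2.51 and 1.35 FPKM in the control RIP against 26.6 and 29.9 FPKM in the CLF RIP, and COR27 at 7.53 and 1.46 FPKM against 47.8 and 44.4 FPKM. Among morning genes, LNK2 was at 100.4 and 67.9 FPKM against 24.2 and 28.5 FPKM, and LHY at 4.42 and 9.99 FPKM against 1.16 and 1.54 FPKM. By limma with Benjamini-Hochberg adjustment, FKF1 passed with an adjusted p of 0.0484 and the other 3 did not.

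TOC1 and ELF4 were higher in the CLF RIP, and a candidate explanation is that plants of the 2 groups were sampled at different times of day. The median log2 fold change of 4 evening genes was 2.59 and that of 10 morning genes -1.12. The difference of 3.71 had an exact two-sided permutation p of 0.00999 over genes, which are not independent. The 4 evening genes were FKF1, LUX, COR27 and ELF3 (0.24), without TOC1 and ELF4. GI, BOA and PRR5 had also been chosen as evening genes but had no tested value. Counts for the clock list, which holds 6 of these 14 genes, had been seen before. Outside the fixed lists the difference was 4.47 over 2 evening and 6 morning genes, with an exact permutation p of 0.0714, the smallest 2 against 6 can give. The labels give no time of day, COR27 is also known to respond to cold, and an effect of the tagged line or of binding to CLF stays open and untested.

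The lower level of photosynthesis genes was set against 2 technical explanations. If abundant mRNAs lay lower in general, random lists matched on mean level could do the same, but the list's median lay at percentile 0 of 10000. The median was -1.52 after median-of-ratios scaling, but that scaling moved the median of all genes from 0.25 to 0.01. It could thus only lower this list, so the test cannot decide on scaling. The list's shift from the median of all genes was -1.49 as deposited and -1.53 after that scaling. A common factor per library moves all genes nearly alike, so this shift could hardly change and does not test scaling either. It states only that the list lay below the median of all genes. No input RNA was analysed here, so a difference in the plants and a difference in bound RNA, as well as swapped labels, remain open.

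Some long loci had values far above those of other long loci, and a candidate explanation is that 1 read assigned to a read-length isoform adds a fixed value. In each library at least 90.9% of loci of 300 bp or more at or above the value of 1 read lay within 1% above a whole multiple of it.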
